A study of Mus musculus with 16 samples.

How the data were processed

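Total RNA of the duodenum and ileum of 8 adult male mice on a C57BL/6N background was sequenced, giving 16 libraries. The mice carried floxed alleles of Neurog3, the transcription factor that starts the enteroendocrine fate in the intestinal epithelium. In 4 of them the Villin-CreERT2 transgene, a tamoxifen-activated recombinase driven by a promoter of the intestinal epithelium, allowed the gene to be deleted; these are called mutants. The other 4 carried the floxed alleles without the transgene and are called controls. Tissue was taken 18 weeks after tamoxifen from mice on standard chow, and each animal gave both tissues, so that the animal number in the labels links a duodenal and an ileal library. Libraries are named here by tissue and by the animal's name in the labels, which starts with NFVCT for mutants and with NF alone for controls. Because controls lacked the recombinase, an effect of the transgene itself cannot be parted from that of Neurog3 loss in these comparisons. The labels give the time after tamoxifen for both genotypes together and do not say separately that controls received it. If they did not, its effect could not be parted either.

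Per the labels' protocols, the libraries were stranded and made from total RNA after removal of ribosomal RNA, with PCR amplification; molecular identifiers are not mentioned, and neither are the part or layers of each tissue that were taken. The submitters' processing notes name bcl2fastq 2.20.0.422, cutadapt 1.10, Bowtie2 2.2.8, STAR 2.5.3a and HTSeq 0.6.1p1 with the genome build mm39, without stating their order; the strand setting of the counting and the annotation release are not given in the sources used here. Per the file headers and its values, the deposited table holds raw read counts per Ensembl gene, not normalised, with 1 column per library and 55359 genes. It holds no rows of unassigned reads. Symbols were taken from a gene name table by Ensembl identifier without its version: 52083 identifiers matched, carrying 98.3% of all counts, and 3276 did not. Where an identifier shared its symbol with a more abundant one (68 cases), only the more abundant kept it. No genome of the files' build was at hand, so no coordinates are given.

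Total counts per library ran from 8213889 to 35076714. A group's floor was set at 3 counts over its 4 libraries; a gene with 0 counts in a group is given as at least so many times lower than in the other group, measured against that floor. For genes with few counts, the ratio is given with an exact binomial 95% interval. Intervals and floors cover counting error only, since PCR copies are not independent molecules. Floors leave out the counting error of the other group, so values given as at least so many times lower or higher are not 95% limits.

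Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM scaling, the default filter on low counts by group, and the quasi-likelihood F test with a robust prior. P-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05 with no limit on fold change. Every adjusted p for a gene in the text comes from this test unless another tool is named. CPM values (counts scaled to a common library size with TMM factors) were computed from the deposited counts and are given as mean ± SD over 4 libraries. The scaling used the libraries of each test, so the CPM of a gene differs slightly between tests. Log2 fold changes carry their standard error (SE), obtained as the fold change over the square root of the F statistic. Fitted fold changes use a prior count of 0.125 and are not printed for genes with 3 or fewer counts in a group.

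Genotype was tested within each tissue on its 8 libraries. The difference of the genotype effects between tissues (ileum minus duodenum) was tested over all 16 libraries, and control ileum was set against control duodenum on 8 libraries. Libraries of the same animal deviated together: the correlation of their deviations from the group means over genes ran from 0.127 to 0.327 in the 8 animals, each above the highest correlation with another animal's library (at most 0.0821). The animal as a block was therefore fitted as the paired alternative for both tests that span the tissues. No animal entered both genotypes, so nothing could be paired in the within-tissue tests. No library pair of a group agreed within sampling noise.

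The text names genes by a rule fixed, with the tests, the alternatives and 47 gene lists, before the data were examined. It takes the lists of enteroendocrine hormones and transcription factors with Chga and Chgb, the 10 largest called changes each way without overlap of the groups and with a mean CPM of at least 1, and up to 4 members of smallest p of each other list. For the interaction it takes the called genes of smallest p, and for the tissue comparison the lists of proximal and distal identity and the 5 largest changes each way. Predicted genes, pseudogenes and receptor or immunoglobulin segments were counted but not named. Some genes that the rule takes are not reported here. Lists with at least 5 tested genes were tested against the other genes with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01 and, as the alternative, with the correlation estimated from the data. Beside camera, the planned test fry of limma asked whether a list's genes differed at all, without setting them against the other genes. A list score is the mean log2 CPM of a list's genes in a library.

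The fits were tested on simulated data drawn from the real means, library sizes and dispersions with known changes. Of 67 genes changed 2-fold, 38 were recovered among 14703 genes with the duodenal settings, 47 among 14951 with the ileal ones, 28 among 15882 in the interaction and 45 among 14976 in the tissue comparison. Of 66 genes changed 4-fold, 59, 59, 53 and 62 were recovered in the same order. At 1.5-fold, 3, 22, 2 and 18 of 67 were recovered. Of the unchanged genes, 4, 6, 5 and 11 were called, which is 3.8, 4.5, 5.7 and 8.1% of the calls. Of 40 simulated lists of 20 genes, only the 1 changed by 1.5-fold was called in each of the 4 designs; genes were drawn independently, so this does not test how the list test handles correlated genes.

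The alternatives covered other scaling factors (those of DESeq2 and the upper quartile), no filter and a stricter filter, the DESeq2 1.42.0 Wald test, limma-voom, a prior that was not robust, all 16 libraries in 1 fit, a surrogate variable from sva 3.50.0, removal of the 10 most abundant genes, and leaving out each library or animal in turn. Alternatives with scores of pancreatic acinar or smooth muscle genes as covariates, without acinar and islet genes, or without the library of highest acinar share in each genotype were added after the data had been seen.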

Results

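Gene expression was measured by RNA sequencing in the duodenum and ileum of mice whose intestinal epithelium lacked Neurog3 and from controls, with 4 libraries in each of the 4 groups. Enteroendocrine cells are the hormone-releasing cells of the gut epithelium, and Neurog3 is needed to form them; the comparisons ask what is lost with them and what else differs in each part of the small intestine 18 weeks later. Animals are named as in the labels, NF for controls and NFVCT for mutants. In the duodenum, controls NF17, NF29, NF32 and NF152 held 14366051, 12291842, 11365476 and 18134135 counts. Mutants NFVCT27, NFVCT38, NFVCT153 and NFVCT190 held 14849973, 17086775, 35076714 and 10096736. In the ileum, the same controls gave 25617964, 9951843, 9513823 and 20306466 counts, and the same mutants 8275675, 15733292, 8213889 and 18093452.

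Neurog3 (ENSMUSG00000044312), the targeted gene, had 0 counts in all 8 mutant libraries. For Neurog3, control libraries held 12 to 37 counts in the duodenum (1.71 ± 0.50 CPM, SD, n = 4) and 8 to 27 in the ileum (1.05 ± 0.19 CPM, n = 4). Against the floor over the group, Neurog3 was at least 45.7-fold lower in the mutant duodenum (at least 23.9-fold without mutant NFVCT153) and at least 16.9-fold lower in the mutant ileum (at least 10.8-fold without mutant NFVCT190).

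In the mutant duodenum the hormone genes of the proximal gut were nearly gone. Gip, the incretin hormone of K cells, went from 53.7 ± 5.6 CPM in controls to 0.093 ± 0.103 CPM (log2 fold change -8.57, SE 0.31, adjusted p = 9.26e-08). Cck, the hormone that empties the gall bladder, fell by 7.31 on the log2 scale (SE 0.47, adjusted p = 0.000126), and the genes for ghrelin (Ghrl, -7.24, SE 0.73) and for the serotonin-making enzyme of enterochromaffin cells (Tph1, -7.81, SE 0.45) fell as far. Sst, Sct and Tac1, which code for somatostatin, secretin and tachykinins, fell less, with log2 fold changes of -2.54 (SE 0.14), -2.59 (SE 0.29) and -2.54 (SE 0.27). Sst kept 5.21 ± 0.66 CPM in the mutants against 30.2 ± 2.7 in controls.

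Of the 9 tested members of the hormone list, 7 fell in the duodenum over all genes tested and 8 adjusted over the list alone. Gcg did not pass over all genes (9.89 ± 1.08 CPM in controls, 1.11 ± 1.24 in mutants, log2 fold change -3.32, SE 1.01, adjusted p = 0.348). Nor did Pyy, which was low in both groups (1.40 ± 1.28 and 1.02 ± 0.90 CPM, -0.64, SE 1.09, adjusted p = 0.955). Of 8 enteroendocrine transcription factors tested, 6 fell, all 8 adjusted over the list alone. Lmx1a had 0 counts in the 4 mutant libraries and was at least 50.8-fold lower (at least 26.6-fold without NFVCT153), Neurod1 kept 0.322% of its control level (95% interval 0.00812 to 1.81%), and Insm1 fell by 3.85 (SE 0.48); Myt1 and St18 did not pass (adjusted p = 0.103 and 0.143). Of 23 other secretory and sensing genes, 4 fell, 13 adjusted over the list alone. Chgb, a granule protein of endocrine cells, went from 213 ± 39 to 2.03 ± 1.06 CPM (-6.67, SE 0.32), while Chga did not pass (-3.61, SE 0.64, adjusted p = 0.0919). Of the pancreatic islet markers, 4 were tested (Ins1, Ins2, Iapp and Ppy) and none was called, adjusted over the list alone included (median 1.296). The islet score of mutants NFVCT27, NFVCT38, NFVCT153 and NFVCT190 was 2.09, 3.14, -2.53 and 3.67, and that of controls NF17, NF29, NF32 and NF152 was 1.97, -0.757, 2.15 and 0.206. In the same order of mutants, Gcg had 0.084, 2.22, 0 and 2.54 CPM and Chga 4.79, 7.81, 1.42 and 14.1 CPM. Pyy had 0.588, 1.63, 0.029 and 2.21 CPM. Whether islet RNA gave these counts was not tested, so they do not show that Pyy is spared.

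**Figure D1:**
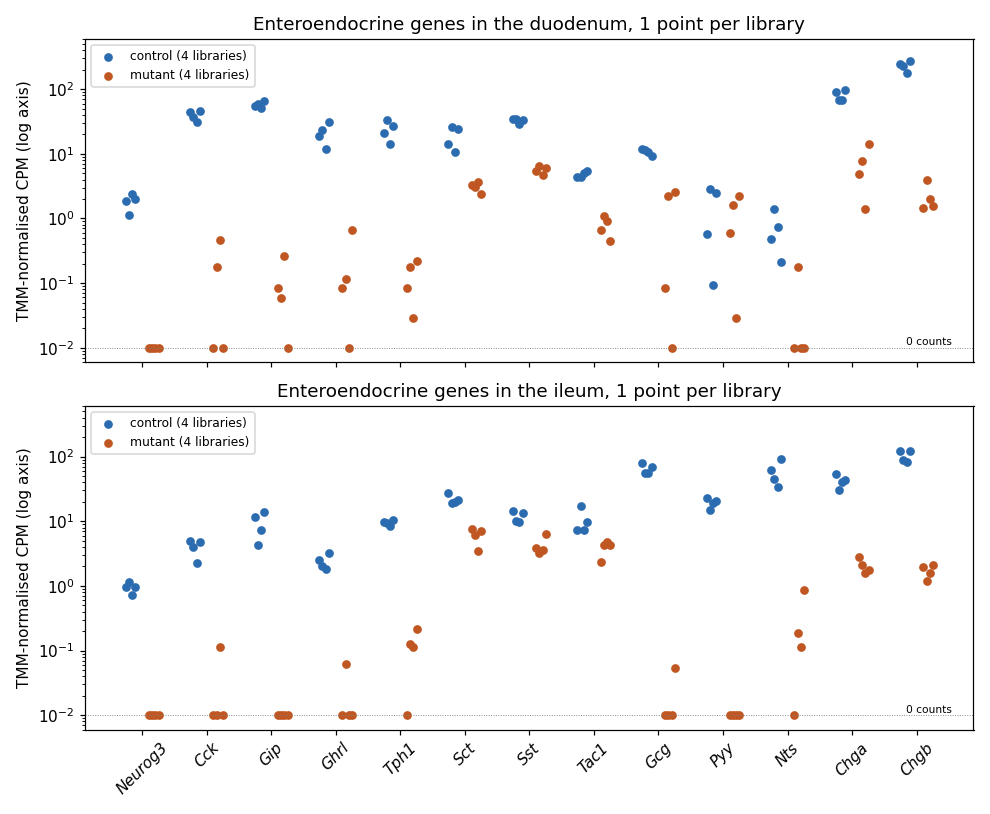
CPM after TMM scaling (log axis, points without counts drawn on the dotted line) of Neurog3, hormone genes and granule genes in each library of the duodenum (top) and ileum (bottom), controls in blue and mutants in orange. All 8 mutant libraries lay on the line for Neurog3, and Sst, Sct and Tac1 kept counts in all 8.

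In all, 58 genes differed by genotype in the duodenum among 14703 tested, 14 higher and 44 lower in the mutants, the called endocrine genes included. Among the largest falls, Afp (alpha-fetoprotein) kept 0.0801% of its control level (95% interval 0.00969 to 0.29%). Adgrg4 had 0 counts in the mutants and was at least 196.8-fold lower (at least 103.1-fold without NFVCT153). Trpa1, an irritant-sensing ion channel of the endocrine secretory and sensing list, went from 9.04 ± 2.01 to 0.797 ± 0.470 CPM (-3.52, SE 0.32, adjusted p = 0.000411). The other large falls were in Vwa5b2, Slc38a11, Gfra3, Stxbp5l, Pzp, Rimbp2 (log2 fold changes from -4.32 to -1.95) and the cytochrome P450 gene Cyp2c55 (88.8 ± 30.2 to 4.45 ± 2.34 CPM, -4.29, SE 0.44). The largest rise was in Esr1, the estrogen receptor gene, from 2.68 ± 1.21 to 40.5 ± 8.2 CPM (3.89, SE 0.30, adjusted p = 0.000306). Mgat4c, a glycosyltransferase gene, rose by 2.70 (SE 0.30) and the class I histocompatibility gene H2-Q10 by 2.15 (SE 0.27). Smaller rises were those of Cpn2 (1.76, SE 0.29) and Ttc39a (0.72, SE 0.12). H2-Q10 belongs to a family of near-identical genes, so its counts are uncertain. Ttc39a lost its call in all 8 fits that left out 1 library (adjusted p up to 0.128), Nkx2-2 of the transcription factors in 7 (0.137) and Cpn2 in 6 (0.0964). Calls were also lost for Rfx6 and Slc38a11 in 4 each (0.0902 and 0.087), Rimbp2 without control NF17 or control NF29 (0.0775), and Cyp2c55 and Stxbp5l without mutant NFVCT38 (0.0531 and 0.0539).

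Genes of cholesterol synthesis were higher in the mutant duodenum. Of 25 tested, 6 rose over all genes and 22 adjusted over the list alone, with a median log2 fold change of 0.78 (camera adjusted p = 9.64e-41, and adjusted p = 0.0248 with an estimated correlation). Cyp51, which removes a methyl group from lanosterol, rose by 1.54 (SE 0.16, adjusted p = 0.00135, 45.5 ± 4.6 to 132 ± 29 CPM). Sqle rose by 1.38 (SE 0.22), Msmo1 by 1.29 (SE 0.21), Lss by 1.09 (SE 0.16) and Hsd17b7 by 0.75 (SE 0.14). Cyp51 kept its call in all 8 fits that left out 1 library, while Sqle and Msmo1 lost theirs in 5 (adjusted p up to 0.141). Hsd17b7 lost its call in 7 and Lss in 2 (without control NF17 or control NF152), with adjusted p up to 0.191 and 0.0775.

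Antigen presentation, interferon gamma and T and NK cell genes were lower in the mutant duodenum. Of 33 genes of antigen presentation and the interferon gamma response, 5 fell over all genes and 31 adjusted over the list alone (median -1.1, adjusted p = 0.0188 with an estimated correlation). Among them were the GTPase gene Iigp1 (-1.78, SE 0.21, adjusted p = 0.00303) and the chemokine gene Cxcl9 (-1.71, SE 0.26). Of 19 T and NK cell genes, 5 fell over all genes and 17 adjusted over the list alone (median -1.19, adjusted p = 0.0248 with an estimated correlation). Cd3e, a chain of the T cell receptor complex, went from 6.43 ± 2.07 to 1.86 ± 0.33 CPM (-1.80, SE 0.28, adjusted p = 0.0193). Lck went from 8.29 ± 1.36 to 3.18 ± 0.62, and Itgae, an integrin of intraepithelial lymphocytes, from 40.2 ± 5.2 to 21.7 ± 4.0. None of the 12 B and plasma cell genes was called, and 1 was lower adjusted over the list alone, Ighm (-0.92, SE 0.17, adjusted p = 0.0537 over all genes). Iigp1 kept its call without any 1 library. The calls of Cxcl9, Itgae and Cd3e were lost in 4, 5 and 6 of 8 such fits (adjusted p up to 0.087, 0.128 and 0.0978) and that of Lck without control NF17 or mutant NFVCT38 (up to 0.0664).

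Other lists of the duodenum rested on few called genes. Xenobiotic metabolism had 1 gene called of 28 (Cyp2c55) and 10 lower adjusted over the list alone, with a median of -0.68 and an adjusted p = 0.23 with an estimated correlation. Its large members Cyp3a11 (1354 ± 825 to 151 ± 124 CPM, -3.16, SE 0.66, adjusted p = 0.115) and Gstm3 (-2.04, SE 0.38, adjusted p = 0.0726) did not pass. Paneth and goblet cell lists had no gene called, 5 of 14 and 7 of 17 higher adjusted over the list alone, and adjusted p = 0.18 and 0.106 with an estimated correlation; Bcas1, a goblet cell gene, had a log2 fold change of 0.66 (SE 0.13, adjusted p = 0.0565) and Ang4, a Paneth cell gene, had 131 ± 37 CPM in controls and 263 ± 49 in mutants (adjusted p = 0.1). Lipid absorption had 0 of 30 genes called. Its member Abca1, a cholesterol exporter, had -1.32 (SE 0.24, adjusted p = 0.0547). None of the 8 proximal identity genes was called, and all 8 had log2 fold changes below 0 (median -0.59). That list had a camera adjusted p = 0.00525, and 0.287 with an estimated correlation. Of 5 distal identity genes 1 was above 0 (median -0.22, adjusted p = 0.434 with an estimated correlation). Whether the pieces came from the same part of the duodenum was not tested.

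Of the duodenal lists, 19 were shifted with the preset correlation and 6 with the estimated one; those 6 are hormones, endocrine transcription factors, endocrine secretory genes, antigen presentation, cholesterol synthesis and T and NK cells. With the preset correlation, 17 of the 35 splits of the 8 libraries shifted at least as many lists, the real one included. Some of these splits kept part of the genotype difference, so this count does not measure chance. Pancreatic acinar genes took 16.04, 8.45, 10.05 and 7.20% of counts in control libraries NF17, NF29, NF32 and NF152. In mutant libraries NFVCT27, NFVCT38, NFVCT153 and NFVCT190 they took 12.9, 1.97, 2.29 and 20.3% (means 10.4 ± 3.9 and 9.36 ± 8.89%, exact permutation test, two-sided, p = 0.8). Without the library of highest acinar share in each genotype, 31 genes were called, 26 of them among the 58, and with the acinar score as a covariate 50, with 34 among the 58. With that covariate Sqle, Msmo1, Hsd17b7, Cyp2c55, Cd3e, Cpn2, Nkx2-2 and Ttc39a lost their calls (adjusted p from 0.0536 to 0.114). Their log2 fold changes with it were 1.26, 1.19, 0.68, -4.255, -1.61, 1.66, -2.13 and 0.73, in that order. Leaving out control NF17, control NF29 or mutant NFVCT38 gave 28, 38 and 27 calls; the DESeq2 Wald test called 310 genes, and 1280 had an unadjusted p under 0.05.

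In the mutant ileum the hormone genes of the distal gut were lost as well. Gcg, which codes for the glucagon-like peptides of L cells, had 1 count over the 4 mutant libraries against 5134 in controls (71.9 ± 11.6 CPM), or 0.0272% of the control level (95% interval 0.000689 to 0.152%). Pyy and Gip had 0 counts in the mutants and were at least 359.2-fold and at least 185.1-fold lower (at least 229.9-fold and at least 118.5-fold without NFVCT190). Nts (neurotensin) went from 64.0 ± 27.3 to 0.311 ± 0.414 CPM (-7.30, SE 0.64, adjusted p = 0.00227) and Tph1 from 10.3 ± 0.8 to 0.122 ± 0.094 (-6.10, SE 0.32, adjusted p = 4.77e-08). All 10 tested hormone genes fell; Sct (-1.87, SE 0.20), Sst (-1.48, SE 0.22) and Tac1 (-1.39, SE 0.30) had the smallest log2 changes of the 10. Tac1 lost its call in 5 of 8 fits without 1 library (adjusted p up to 0.0807).

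Of 8 endocrine transcription factors, 7 fell in the ileum: Lmx1a had 0 counts in the mutants (at least 18.8-fold lower, at least 12.1-fold without NFVCT190), and Neurod1 kept 1.45% of its control level (95% interval 0.174 to 5.3%). Insm1 went from 2.06 ± 0.12 to 0.364 ± 0.325 CPM (adjusted p = 0.00923), and Rfx6, Isl1 and Myt1 fell by 3.53 (SE 0.53), 3.59 (SE 0.63) and 1.82 (SE 0.39). Of the 6 fits without 1 library that tested Myt1, it lost its call in 3, without control NF32, mutant NFVCT38 or mutant NFVCT190 (adjusted p up to 0.0615). St18 did not pass (-0.37, SE 0.29, adjusted p = 0.618). Chgb fell by 5.96 (SE 0.20), Chga by 4.37 (SE 0.21), and the fatty acid receptor gene Ffar1 kept 0.873% of its control level (95% interval 0.022 to 4.94%). Of 24 secretory and sensing genes, 8 fell and 1 rose (adjusted p = 0.0703 with an estimated correlation). Only the hormone and transcription factor lists, of 23 shifted with the preset correlation, held with the estimated one (adjusted p = 0.000887 and 0.0176). With the preset correlation, 9 of 35 splits shifted at least as many, the real one included. Some of these splits kept part of the genotype difference, so this count does not measure chance.

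The ileum had many more calls than the duodenum: 490 genes among 14951, 264 higher and 226 lower in the mutants. The smooth muscle score was also higher in the mutant ileum (8.17 ± 0.20 against 7.56 ± 0.21, exact permutation test, two-sided, p = 0.0286, the smallest p that 4 against 4 allows), beside every group of ileal genes described here. The largest rises were in Pla2g4c, a phospholipase gene (27.5 ± 14.3 to 2352 ± 1249 CPM, 6.43, SE 0.73, adjusted p = 0.00901), and Retnlb, a goblet cell antibacterial protein (2.98 ± 1.24 to 80.6 ± 36.5 CPM, 4.75, SE 0.54, adjusted p = 0.00763). Esr1 rose from 4.41 ± 1.61 to 56.1 ± 6.4 CPM (3.62, SE 0.21). Other large rises were those of Cfap61 (4.52, SE 0.42), Cyp2d34 (4.39, SE 0.43), Cyp2d9 (3.53, SE 0.49), Sprr2a3 (3.08, SE 0.56), Prom2 (2.40, SE 0.55), Igfbp2 (2.33, SE 0.46) and Gsdmc2 (2.25, SE 0.41). The Cyp2d, Sprr2a and Gsdmc genes are families of close copies whose counts are uncertain. The calls of Sprr2a3, Prom2 and Gsdmc2 were each lost in 6 of 8 fits without 1 library (adjusted p up to 0.128, 0.111 and 0.111), that of Igfbp2 without mutant NFVCT38 (0.0526). The falls outside the endocrine lists included Adgrg4 (0 counts in mutants, at least 37-fold lower, at least 23.7-fold without NFVCT190), Afp (1.22% of control, 95% interval 0.25 to 3.59%), and Fam151a (-3.50, SE 0.60). Fam151a lost its call with limma-voom. Others were Gfra3 (-2.64, SE 0.46), the neuropeptide gene Npy (-2.60, SE 0.51), Nr2e3 (-2.55, SE 0.41) and Ces1g (-2.47, SE 0.39). Cyp2c55 (-5.35, SE 0.97) and Ubd (-3.37, SE 0.58) fell too, and each lost its call in 7 of 8 fits without 1 library (adjusted p up to 0.139 and 0.101).

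Most genes of the carbohydrate digestion and uptake list were higher in the mutant ileum, but the list did not pass with an estimated correlation. Of 14, 10 rose and 11 rose adjusted over the list alone (median 0.99, adjusted p = 0.0703 with an estimated correlation). Sis, the brush border sucrase-isomaltase, went from 5431 ± 1017 to 20594 ± 2072 CPM (1.92, SE 0.16, adjusted p = 1.2e-05). The maltase gene Mgam rose by 1.05 (SE 0.14) and the glucose transporter gene Slc5a1 by 0.96 (SE 0.12). Of 16 glycolysis genes 4 rose (Pkm 1.19, SE 0.14; Ldha 0.73, SE 0.14; Gpi1 0.73, SE 0.14; Pfkl 0.56, SE 0.12), 8 adjusted over the list alone (adjusted p = 0.237 with an estimated correlation); Pfkl lost its call in 3 of 8 fits without 1 library (adjusted p up to 0.0796).

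Among 16 fatty acid synthesis genes 4 rose, 10 adjusted over the list alone (adjusted p = 0.0719 with an estimated correlation). The malic enzyme gene Me1 rose by 2.24 (SE 0.24, adjusted p = 0.000894), the desaturase gene Scd1 by 1.68 (SE 0.23), Thrsp by 1.55 (SE 0.29) and the carbohydrate-responsive factor Mlxipl by 1.03 (SE 0.16). Thrsp lost its call without control NF32 or control NF152 (adjusted p up to 0.0658). Of 30 lipid absorption genes 3 rose, including Acsl3 (0.94, SE 0.12) and Dgat2 (0.83, SE 0.14), and 2 fell, including Abca1 (-0.72, SE 0.14). The list was not shifted (median 0.03, adjusted p = 0.297). None of 25 cholesterol synthesis genes was called and 5 were higher adjusted over the list alone (adjusted p = 0.371 with an estimated correlation; Cyp51 0.58, SE 0.18, adjusted p = 0.107). Among 22 genes of peptide and amino acid absorption 5 fell, including the peptidase genes Naaladl1 (-0.63, SE 0.12), Anpep (-0.80, SE 0.16) and Mep1b (-0.59, SE 0.12), 8 adjusted over the list alone (adjusted p = 0.135 with an estimated correlation). Anpep lost its call without mutant NFVCT38 (adjusted p = 0.0551). Of 27 xenobiotic metabolism genes 6 fell, including Ces2a (-1.35, SE 0.15) and Gstm3 (-1.98, SE 0.28), 11 adjusted over the list alone (adjusted p = 0.256 with an estimated correlation).

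**Figure D2:**
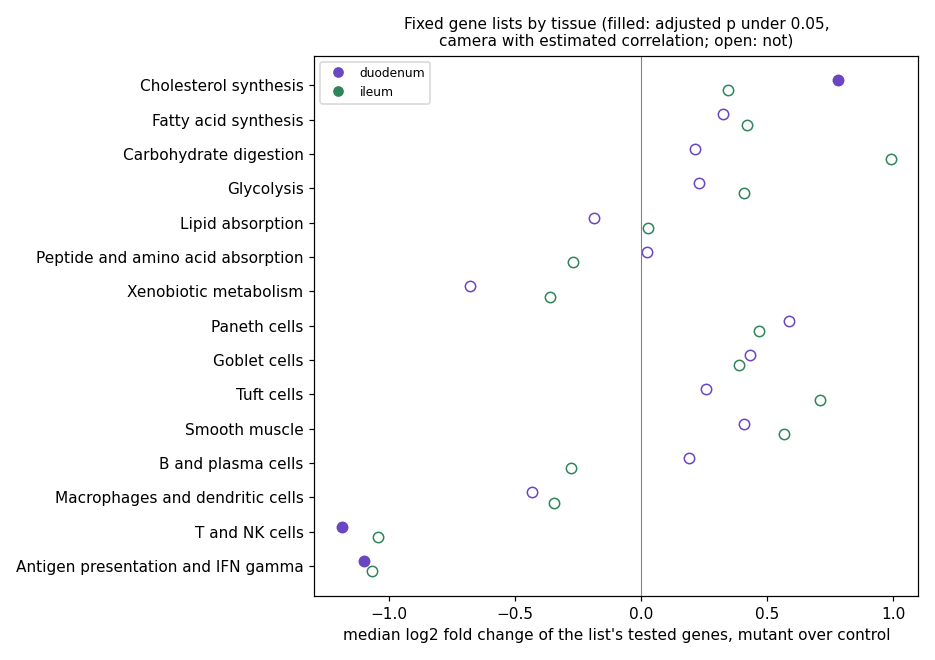
Median log2 fold change, mutant over control, of 15 gene lists in the duodenum (purple) and ileum (green); filled points passed camera with an estimated correlation. Cholesterol synthesis (median 0.78), T and NK cells (-1.19) and antigen presentation are filled in the duodenum and none of the 15 in the ileum.

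Some secretory and tuft cell genes were higher in the mutant ileum, but none of their lists passed camera with an estimated correlation. With fry, which does not set a list against the other genes, the goblet, tuft and Paneth cell lists passed (adjusted p = 0.00689, 0.0157 and 0.0177). Of 15 tuft cell genes 7 rose, among them Avil (1.11, SE 0.19), the taste channel gene Trpm5 (0.94, SE 0.16) and Dclk1 (0.70, SE 0.16), 10 adjusted over the list alone (adjusted p = 0.108 with an estimated correlation). Of 17 goblet cell genes 5 rose, 8 adjusted over the list alone (adjusted p = 0.0703 with an estimated correlation), with Clca1 at 0.92 (SE 0.16), Spink4 at 0.74 (SE 0.12), Spdef at 0.64 (SE 0.15) and Bcas1 at 0.63 (SE 0.11). Of 15 Paneth cell genes 4 rose, 8 adjusted over the list alone (adjusted p = 0.108 with an estimated correlation), with Ang4 at 1.47 (SE 0.17) and Mptx2 at 0.90 (SE 0.15), both members of families of close copies. Epithelial defence had 2 of 16 genes higher, Retnlb and Il18 (1.09, SE 0.19), with an adjusted p = 0.135 with an estimated correlation. Dclk1 and Spdef each lost their call in 6 of 8 fits without 1 library (adjusted p up to 0.127 and 0.0957). Of 14 stem cell genes 1 fell, Olfm4 (677 ± 81 to 284 ± 50 CPM, -1.25, SE 0.14, adjusted p = 0.000158), and 1 rose, Prom1 (0.56, SE 0.13). The call of Prom1 was lost in 6 of 8 such fits (adjusted p up to 0.1), and the list was not shifted (adjusted p = 0.394). None of 26 proliferation genes was called. Fabp6, the ileal bile acid binding protein, went from 3302 ± 989 to 858 ± 456 CPM and did not pass (-1.95, SE 0.46, adjusted p = 0.0864). Neither did Slc51a (-0.27, SE 0.11, adjusted p = 0.248) or Fgf15 (1.28, SE 1.1, adjusted p = 0.668). Of the 8 distal identity genes only 1, Fgf15, had a log2 fold change above 0 (median -0.13). That list had a camera adjusted p = 0.0486, and 0.165 with an estimated correlation. The proximal identity list was not shifted (camera adjusted p = 0.572).

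Some T and NK cell and interferon gamma genes were lower in the mutant ileum too, but neither list passed with an estimated correlation. Of 33 genes of antigen presentation and the interferon gamma response 12 fell, 30 adjusted over the list alone (median -1.07, adjusted p = 0.108 with an estimated correlation). They included Gbp8 (-1.93, SE 0.20, adjusted p = 0.000102), Gbp4 (-1.24, SE 0.22) and Ciita, the master regulator of class II genes (-1.27, SE 0.23). The Gbp genes are close copies. Of 19 T and NK cell genes 5 fell, 13 adjusted over the list alone (median -1.04, adjusted p = 0.135 with an estimated correlation). They included Klrd1 (-1.94, SE 0.32), Cd3e (-1.90, SE 0.38), Lck (-1.24, SE 0.24) and Trac (-1.18, SE 0.25). None of the 13 B and plasma cell genes was called. Ciita lost its call without control NF32 (adjusted p = 0.0507) and Trac in 3 of 8 fits without 1 library (up to 0.0613). Siglecf, the 1 called gene of 5 tested in the granulocyte list, had 1.04 (SE 0.25, adjusted p = 0.0385). It lost its call in 6 of 8 such fits (up to 0.131), and the list was not shifted (camera adjusted p = 0.237).

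**Figure D3:**
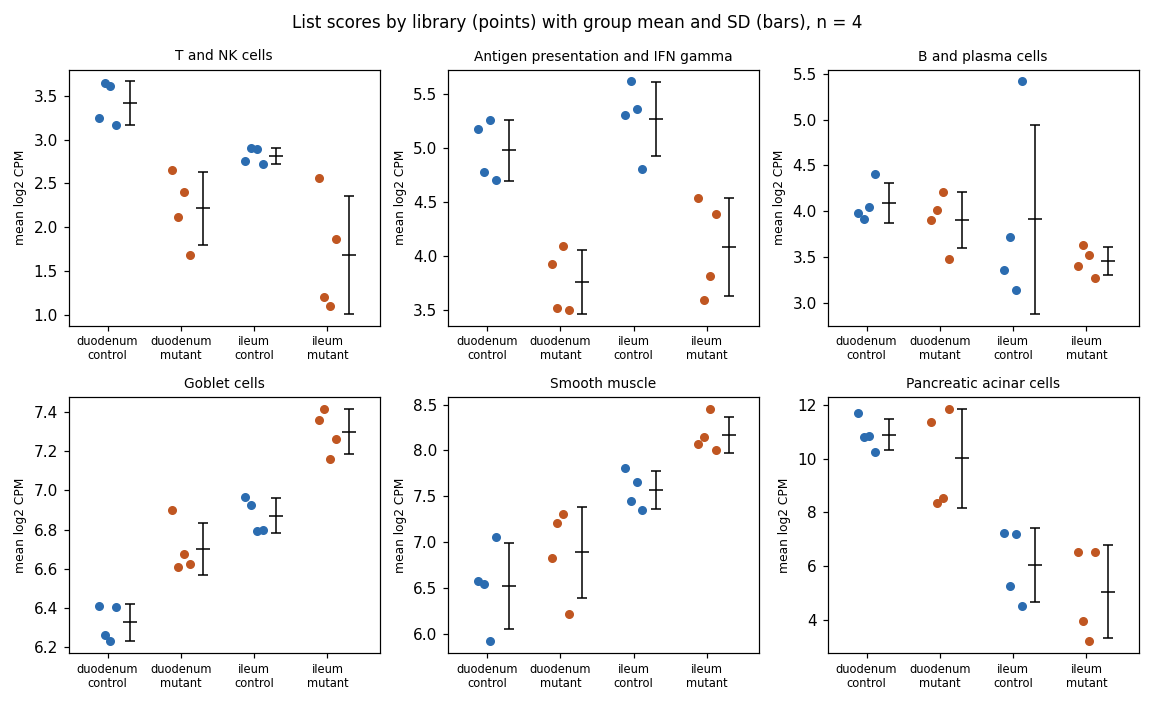
Mean log2 CPM of 6 gene lists in each library (points, controls blue and mutants orange) with group mean and SD (n = 4 each). T and NK and antigen presentation scores of all 4 mutant libraries lay below those of all 4 controls in both tissues, and the smooth muscle score of the mutant ileum (8.17 ± 0.20) lay above that of the controls (7.56 ± 0.21).

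Of 13 smooth muscle genes 7 rose in the mutant ileum, 10 adjusted over the list alone (adjusted p = 0.135 with an estimated correlation). Among them were Des (0.97, SE 0.17), Cnn1 (0.92, SE 0.15), Tagln (0.70, SE 0.10) and Myl9 (0.62, SE 0.13). Myl9 lost its call without control NF152 or mutant NFVCT38 (adjusted p up to 0.0531). With the smooth muscle score as a covariate 35 genes were called, 29 of them among the 490. The log2 fold changes of the 490 genes kept their sign, their median ratio to those without it was 0.957, and their SE grew by a median factor of 1.81. Of 16 enteric neuron genes 2 fell, Npy and Vip (-0.81, SE 0.16). The epithelial growth factor gene Ereg (0.97, SE 0.16) and Igf1 (0.85, SE 0.14) rose, the 2 called members of 11 growth factor genes (adjusted p = 0.165 with an estimated correlation), as did Tacr1, a tachykinin receptor gene (1.30, SE 0.21), the only called member of 10 gut hormone receptor genes. Without control NF17, control NF32 or mutant NFVCT38 the ileum had 293, 277 and 272 calls, the DESeq2 Wald test called 875 genes, and 194 genes changed over 2-fold.

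Calls were shared between the tissues. Of the genes called in the duodenum, 33 were called in the ileum with the same sign, 3 higher (Esr1, H2-Q10 and Ttc39a) and 30 lower, and none with the opposite sign. Independent lists of these lengths would share 0.23 higher and 0.592 lower genes; both tissues came from the same 8 animals, so chance differences between animals are shared as well. Without control NF17 or mutant NFVCT38 in both tissues, 17 calls were shared. Of 435 genes called in the ileum, endocrine lists left out, 384 (88.3%) had the same sign in the duodenum. As many genes of smallest p in the 34 other splits of the animals had the same sign in 34 to 85.5% (median 67.05%).

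The test of the difference between the tissues called 7 genes among 15882, 6 with the higher log2 change in the ileum. Trpa1 was lower in the mutant duodenum and not in the mutant ileum (2.42 ± 1.01 CPM in control ileum, 2.60 ± 0.93 in mutant ileum, difference 3.59, SE 0.48, adjusted p = 0.00403). Sis rose in the ileum and had 7060 ± 786 and 8417 ± 1403 CPM in control and mutant duodenum (difference 1.69, SE 0.28, adjusted p = 0.0262). Reg4, an epithelial lectin, had 113 ± 40 and 43.3 ± 7.5 CPM in control and mutant duodenum and 168 ± 51 and 381 ± 101 CPM in the ileum (2.56, SE 0.39). Pla2g4c (6.60, SE 0.97), the amino acid oxidase gene Dao (1.94, SE 0.27) and the transporter gene Slc16a6 (1.26, SE 0.19) also had the higher change in the ileum, and Mgat4c, expressed at 666 ± 96 CPM in control ileum, the lower one (-2.78, SE 0.32, adjusted p = 0.000819).

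Only Mgat4c of the 7 kept its interaction call in every fit that left out 1 animal. Dao and Trpa1 lost theirs without mutant NFVCT38 (adjusted p = 0.0679 and 0.053), and Reg4, Sis, Slc16a6 and Pla2g4c theirs in 5, 6, 6 and 7 of 8 such fits (up to 0.229, 0.296, 0.133 and 0.341). With the animal as a block 16 genes were called in place of 7, without Sis (adjusted p = 0.0836), and the DESeq2 Wald test called 38; leaving out 1 animal gave from 1 (without mutant NFVCT38) to 9 calls. Of the lists, carbohydrate digestion had the smallest p with the preset correlation (median difference 0.76, adjusted p = 1.29e-20, and adjusted p = 0.239 with an estimated correlation).

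**Figure D4:**
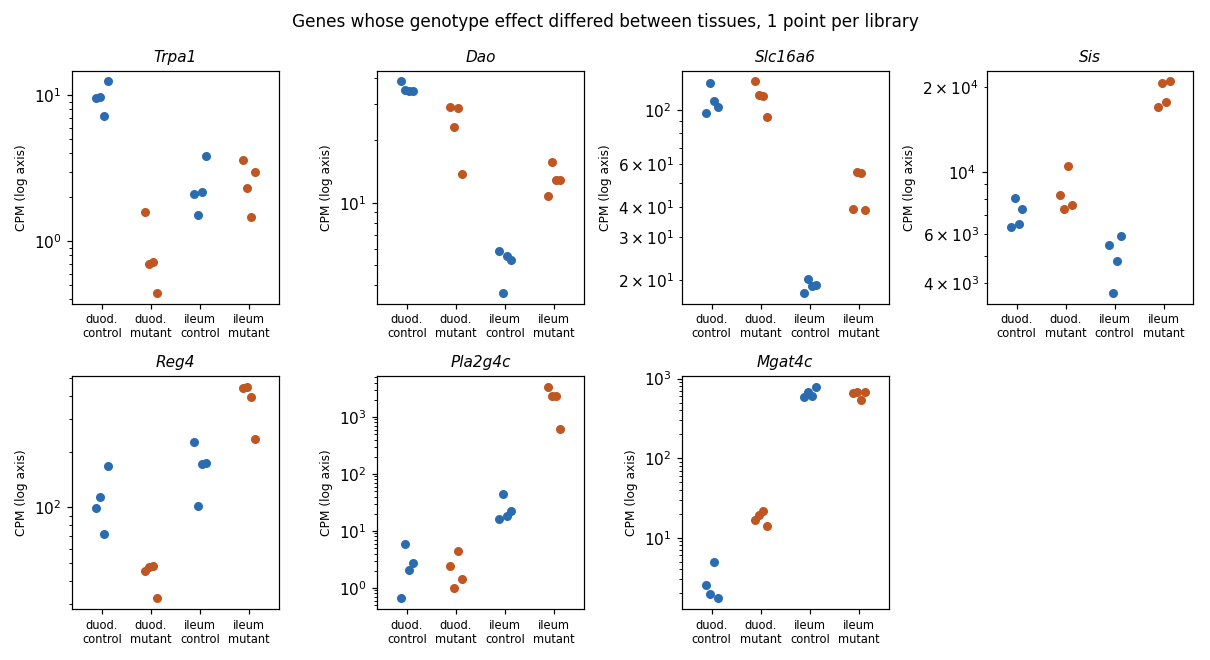
CPM (log axes) of the 7 genes whose genotype effect differed between tissues, 1 point per library, controls in blue and mutants in orange. Mgat4c is near 666 CPM in the control ileum and 2.78 CPM in the control duodenum, where the mutants reached 17.9 CPM.

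Control ileum and duodenum differed in 5372 of 14976 genes, 2568 higher in the ileum and 2804 lower. With upper-quartile factors 2902 were higher and 2480 lower, so the balance of directions depends on the scaling. Markers of other tissue differed as well: all 18 pancreatic acinar genes were lower in the ileum (median -4.59), and 12 of 13 smooth muscle genes (median 1.03) and all 6 adipocyte genes (median 4.83) were higher, with the same counts adjusted over the list alone. These lists had adjusted p = 0.428, 0.507 and 0.507 with an estimated correlation. All 8 genes of the distal identity list were higher in the ileum, and the list passed camera with an estimated correlation (adjusted p = 0.0023). Fabp6 had 3092 ± 929 CPM in the ileum against 0.223 ± 0.156 in the duodenum (13.65, SE 0.42, adjusted p = 1.4e-10). The bile acid transporter gene Slc10a2 had 1277 ± 260 against 1.67 ± 0.64 (9.52, SE 0.29). Osr2 and Fgf15 had 0 counts in the duodenum and were at least 445.1-fold and at least 57.1-fold higher. Without the duodenal library of NF152 these bounds were at least 287.6-fold and at least 36.9-fold, and without the ileal library of NF152 the Fgf15 bound was at least 22.99-fold. Slc51a, Slc51b and Cubn had log2 changes of 2.02 to 4.68. Of 8 genes of the proximal identity list 7 were lower in the ileum, and the list did not pass camera with an estimated correlation (adjusted p = 0.0698). Among the 7 were the transcription factor genes Pdx1 (-5.13, SE 0.29), Onecut2 (-3.62, SE 0.20) and Gata4 (-3.18, SE 0.29). The others were the calcium-binding protein gene S100g (-4.88, SE 0.89), the iron genes Slc40a1 (-2.89, SE 0.29) and Slc11a2 (-1.64, SE 0.28), and lactase (Lct, -1.45, SE 0.34). Cybrd1 did not pass (-1.38, SE 0.58, adjusted p = 0.11).

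The largest rises towards the ileum outside the lists were Slc6a14 (0 counts in the duodenum, at least 4202-fold higher, at least 2715-fold without the duodenal library of NF152), Slc34a2 (12.14, SE 0.41) and Tmigd1 (10.19, SE 0.41), and the largest falls included Pla2g1b, a pancreatic phospholipase gene (-6.21, SE 0.91), Cyp2c29 (-5.37, SE 1.51) and Hamp2, which had 2 counts in the ileum and 204 in the duodenum. Cyp2c29 lost its call in each of the 4 fits without 1 animal (adjusted p up to 0.122), Fgf15 in 3 (up to 0.0921) and Lct without control NF152 (0.079). Without control NF17 the comparison called 3443 genes, 1750 genes changed over 2-fold, and with the animal as a block 5897 were called.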

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

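The tests of signs shared between the tissues, lymphoid follicles, mucosa share, transgene reads, acinar RNA and library spread were chosen after the results were seen; the counts over splits of the animals were planned, but what they would show was written down only after they had been run.

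T and NK cell and interferon gamma lists were shifted down in the duodenum (adjusted p = 0.0248 and 0.0188 with an estimated correlation) but not in the ileum with that correlation (0.135 and 0.108). The T and NK score changed by -1.21 (SE 0.24) in the duodenum and -1.13 (SE 0.34) in the ileum, each with an exact two-sided permutation p of 0.0286. Lymphoid follicles in the control pieces stay open: the change of the B and plasma cell score stood above that of the T and NK score by 1.018 (SE 0.261) in the duodenum and 0.679 (SE 0.674) in the ileum, but the B cell gene Ighm was lower in the duodenum (-0.92, SE 0.17). Ileal control NF152 had 41.4 CPM of Ms4a1 (chosen after its values were seen) and a B and plasma score of 5.42. Its T and NK score (2.72) and antigen presentation score (4.80) were the lowest of the ileal controls. The other ileal controls had B and plasma scores of 3.36, 3.72 and 3.14, near those of the mutants (3.26 to 3.63). These values do not tie the lower ileal T cell genes to follicles. A lower share of mucosa in the mutant pieces would lower epithelial secretory genes too, but the mean goblet, Paneth and tuft score rose by 0.400 (SE 0.0906) in the duodenum and 0.535 (SE 0.101) in the ileum. Some of these genes were themselves called higher in the mutant ileum, so their score is no neutral gauge of the share and cannot decide this. The smooth muscle score of the ileum rose by 0.603 (SE 0.144, exact permutation p = 0.0286), as a lower share would give. A lower share of mucosa stays open. Neither an effect of Neurog3 loss on lymphocytes nor one of the transgene was tested.

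Esr1 was higher in all 8 mutant libraries. A candidate explanation is reads from the estrogen receptor part of CreERT2, which the Villin promoter drives. The Esr1 excess over controls, divided by the CPM of Vil1 (chosen after its values were seen), had a ratio of ileum to duodenum of 1.12 (SE 0.151), as transgene reads would give. A rise of the mouse gene itself stays open, because the counts are per gene and not per exon.

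The duodenum had 58 calls and the ileum 490 (51 and 194 over 2-fold), while the test of the difference called 7 genes. Varying acinar RNA would hide duodenal calls. With the acinar score as a covariate 50 genes were called, 34 of the 58 among them. A covariate in a fit of 8 libraries costs calls by itself, and this one lowered the ileal calls from 490 to 349. The fit therefore cannot decide, and varying acinar RNA stays open. Without acinar and islet genes 65 genes were called, all 58 among them. A wider spread between duodenal libraries is a candidate explanation for part of it: with the duodenal and ileal settings 4.5 and 32.8% of simulated 1.5-fold changes were recovered, 56.7 and 70.1% of 2-fold and 89.4% of 4-fold changes in both, and with all 16 libraries in 1 fit the counts were 151 and 382. Of 435 ileal calls outside the endocrine lists, 384 (88.3%, other splits 34 to 85.5%) had the same sign in the duodenum with a median ratio to the ileal change of 0.47, while 38 duodenal calls had a median ratio of ileum to duodenum of 0.797, and selection lowers both ratios. A smaller effect in the duodenum stays open. The smooth muscle score differed by genotype in the ileum (exact permutation p = 0.0286) and did not pass in the duodenum (exact permutation p = 0.343). With it as a covariate, chosen after the data had been seen, the ileum had 35 calls. Genotype accounted for 71.7% of that score's variance, so this fit cannot part tissue composition from genotype.

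Of 35 splits of the animals, only the real one (1 of 35) gave as many calls in the duodenum (58, highest other 1), in the ileum (490, highest other 6), in the interaction (7, highest other 0) and shared by both tissues (33, highest other 1). A share of 1 in 35 is the smallest that these splits allow. Every other split mixes the genotypes and puts their difference into the spread, so its low count does not show how many calls chance would give. Between the tissues 1 of 35 splits, the real one, gave as many as 5372 calls (highest other 0), but splits that mix the tissues put the tissue difference into the spread. The 8 splits that part all 4 pairs are too few for a share under 0.05. For lists with the preset correlation, 17 splits shifted at least 19 lists in the duodenum (highest other 31). In the ileum 9 shifted at least 23 (highest other 28). The highest other split of each tissue had only 1 mutant on 1 side, so it kept part of the genotype difference. Splits with 2 mutants on each side shifted at most 20 lists in the duodenum and 19 in the ileum. These counts do not tell how many lists chance would shift, and chance was not excluded. With the estimated correlation only the real split gave 6 lists in the duodenum (highest other 0) and 2 in the ileum (highest other 1).

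The genotype effect differed between tissues, as ileum minus duodenum on the log2 scale, for Trpa1 (3.59), Dao (1.94), Slc16a6 (1.26), Sis (1.69), Reg4 (2.56), Pla2g4c (6.60) and Mgat4c (-2.78); with the animal as a block Sis was no longer called (adjusted p = 0.0836). With the preset correlation it also differed for 11 lists, none of which passed with an estimated one, with median differences of 0.292 for lipid absorption, 0.26 for fatty acid oxidation, -0.571 for cholesterol synthesis, 0.755 for carbohydrate digestion, -0.308 for peptide and amino acid absorption, 0.27 for xenobiotic metabolism, 0.183 for glycolysis, 0.67 for villus tip genes, 0.515 for tuft cells, -1.70 for adipocytes and 0.21 for immediate early genes.

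In 26 of 512 groups of 4 libraries (5.08%, where chance gives about 1 in 20), 1 library stood apart, its gap to the nearest other taking the given share of the group's range. In the duodenum these were mutant NFVCT190 for Myt1 (0.837), control NF152 for Stxbp5l (0.911), control NF29 for Msmo1 (0.868), Ang4 (0.873) and Cyp2c29 (0.839), mutant NFVCT38 for Scd1 (0.894) and control NF17 for Dao (0.837). In the ileum they were mutant NFVCT27 for Tac1 (0.84), Pkm (0.911), Cyp2d9 (0.897) and Tacr1 (0.907), control NF152 for Ces1g (0.838) and Fgf15 (0.927), mutant NFVCT38 for Il18 (0.877), control NF32 for Gbp5 (0.981), control NF17 for Tagln (0.88), mutant NFVCT153 for Cfap61 (0.909) and control NF29 for Cubn (0.91). Among list scores they were ileal mutant NFVCT38 for endocrine transcription factors (0.84), duodenal control NF29 for lipid absorption (0.84), ileal control NF152 for glycolysis (0.877), duodenal mutant NFVCT190 for oxidative phosphorylation (0.843) and stem cells (0.97), ileal control NF29 for granulocytes (0.979), ileal control NF17 for blood cells (0.896) and ileal mutant NFVCT190 for the circadian clock (0.906).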

How the results depend on the processing

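The covariate fits, the fit without acinar and islet genes and that without the libraries of highest acinar share were chosen after the data had been seen. No gene called both in the main fit and in an alternative changed sign between them, in any comparison. This count leaves out genes that lost their call. No scaling moved the median of all genes by over 0.1. Without a filter the counts were 169 in the duodenum, 1096 in the ileum, 15 for the interaction and 101 shared, and with the DESeq2 Wald test 310, 875, 38 and 150. A fit of all 16 libraries called 151 genes in the duodenum and 382 in the ileum. Limiting calls to a log2 change over 1 left 194 in the ileum and 1750 between the tissues. Without the library of highest acinar share in each genotype the duodenum had 31 calls, from 3 libraries a group. With the smooth muscle score as a covariate the ileum had 35: genotype accounted for 71.7% of that score's variance, so the SE grew. Ang4 went from 1.47 (SE 0.17) to 1.26 (SE 0.33, adjusted p = 0.203) and Olfm4 from -1.25 (SE 0.14) to -1.17 (SE 0.26, adjusted p = 0.0976), while Sis and Gcg passed (adjusted p = 0.0109 and 1.72e-08). Only 29 of the 490 calls were kept. Among the calls lost were those of Neurog3, Gip, Nts, Sct, Sst, Lmx1a, Insm1, Retnlb, Pla2g4c, Me1, Mgam, Slc5a1, Gbp8 and Cd3e. With the acinar score as a covariate the ileum had 349 calls, 325 of them among the 490. With the estimated correlation 6 lists were shifted in the duodenum and 2 in the ileum. With fry, more ileal lists passed, among them carbohydrate digestion (adjusted p = 0.00764) and fatty acid synthesis (0.0138). Antigen presentation (0.0206), T and NK cells (0.0219) and smooth muscle (0.0263) passed it too. Glycolysis, xenobiotic metabolism and cholesterol synthesis did not (0.0525, 0.077 and 0.145). With the animal as a block, 16 genes were called in the interaction and 5897 between the tissues, and Sis lost its interaction call; the block changed no other call of a named gene. Leaving out 1 library or animal gave 27 to 61 genes in the duodenum, 272 to 472 in the ileum, 1 to 9 for the interaction, 3443 to 4787 between the tissues and 17 to 31 shared, with 14 to 21 lists in the duodenum and 19 to 25 in the ileum. Of the named called genes, 23 of 42 in the duodenum, 71 of 91 in the ileum, 1 of 7 in the interaction and 18 of 21 between the tissues passed in every such fit that tested them. In the ileum the filter on low counts left Neurog3, Isl1, Rfx6, Myt1, Npy and Cyp2d9 tested in 6 of the 8 fits and Vwa5b2 in 4. Other causes were not tested.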

Other observations

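The test of type 2 cytokines was chosen after the result was seen. Of 19 circadian clock genes 2 were called in the mutant ileum: Bhlhe40 rose by 1.05 (SE 0.12, adjusted p = 0.000242) and Ciart by 1.38 (SE 0.34, adjusted p = 0.0416), the latter not called in 7 of 8 fits without 1 library (adjusted p up to 0.155). Arntl had -0.77 (SE 0.20, adjusted p = 0.0675), and the list was not shifted (adjusted p = 0.207).

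The ileal rise of Retnlb, Pla2g4c, Sprr2a3, Gsdmc2 and tuft cell genes may come with a type 2 cytokine response. Il4, Il5 and Il13, chosen after the result was seen, had 4 counts over the 4 mutant ileum libraries and 4 over the controls, too few to decide.

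Residual counts of Gcg and of the islet gene Ins2 in the mutant duodenum were uneven, while those of Sst were not. In mutants NFVCT27, NFVCT38, NFVCT153 and NFVCT190, Gcg had 0.084, 2.22, 0 and 2.54 CPM, Ins2 (chosen after its values were seen) 15.1, 21.0, 0.116 and 50.2 CPM, and Sst 5.46, 6.47, 4.78 and 5.96 CPM. Acinar scores of the duodenum and ileum correlated over the 8 animals (Pearson r 0.889, exact permutation p = 0.00283; Spearman rho 0.81, exact p = 0.0218; 1 relation computed). Without the 2 animals farthest from the median r was 0.718 (exact p = 0.119), which did not pass with the 6 animals left.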
